A study of Homo sapiens with 6 samples.

How the data were processed

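The samples were 3 untreated (control) and 3 alpha lipoic acid libraries of hemogenic endothelial cells derived from the H1 line, sorted on day 8 at 1000 cells per library, with amplified polyA cDNA made from each aliquot. The deposited values were raw counts per gene symbol, which the authors made with HISAT2 and featureCounts on hg38, with DESeq2 also named, per the submitters' processing notes. Versions, options, gene annotation, strand setting and the handling of reads with several alignments were not given in the sources used here. Every value was a whole number, and no column of the count table was left unused.

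Counts were read as deposited for 29436 gene symbols. In 4 libraries (lipoic acid replicates 1 to 3 and untreated replicate 1) 99.13% to 99.34% of nonzero counts were even, against 52.01% and 51.97% in untreated replicates 2 and 3, so a count unit there can stand for less than an independent read. Total counts ran from 30041494 to 41351951 per library, and with even counts halved a floor of 3 independent counts over a group lay at 0.0393 CPM for the untreated and 0.053 CPM for the lipoic acid group. The cDNA was amplified by PCR and no molecular barcodes are mentioned, so the floors and counting intervals cover counting error alone. The labels do not say whether replicates came from separate cultures. The p values therefore measure only the spread between these libraries, which may be technical.

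Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with its default settings by group (13780 tested), libraries were scaled by TMM, and lipoic acid minus untreated was tested with the edgeR quasi-likelihood F test with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher (rose) or lower (fell). Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries, and folds are fitted by edgeR unless given as bounds. The common biological coefficient of variation was 0.137. For a gene at 0 in every library of a group, the fold was bounded against that floor. For a gene with 1 to 3 counts in a group, the ratio of counts, even counts halved, was given with its exact binomial interval at 95%. Sort gate levels and library quality values were compared by exact two-sided permutation tests, in which 3 against 3 gives no p under 0.1.

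There were 38 gene lists, covering the sort gate, hemogenic transcription factors, HOXA and HOXB genes, pan-endothelial, arterial, venous, NRF2, antioxidant, NADPH oxidase, lipoate, hypoxia, glycolysis, respiratory chain, mitochondrially encoded, ribosomal protein, S-phase, G2/M, p53, ATF4 and integrated stress response, endoplasmic reticulum, heat shock, NF-kB, interferon, immediate early, Notch, TGF-beta and BMP, Wnt, cholesterol and metal-handling genes. The same number includes markers of erythroid, megakaryocytic, blood and myeloid, mesenchymal, cardiac, pluripotent, epithelial, endoderm and hepatic, and neural cells. The 36 lists with at least 4 tested members were tested with camera in limma at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated for each list and with fry. Of the 76 respiratory chain genes 61 were found in the count table, and the others, ATP synthase subunits, were not analysed here. A further 5 lists (cytosolic and mitochondrial aminoacyl-tRNA synthetases, proteasome, lysosome and autophagy, and basement membrane) were added after the first results were seen.

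The tests, the 38 lists, most other settings and the rule for naming genes were chosen before the data were examined. The rule named the 4 gate genes, the 12 genes with the largest fitted rise and the 12 with the largest fitted fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, and up to 4 called members of each list with the lowest p. Genes with clone or locus style names, pseudogenes and genes that tell sex apart were left out of the sets of 12. EPCAM, ALB and genes named in the closing part on added lists fell outside this rule and were chosen for the tests reported with them. Positions and overlaps of exons with other genes came from GENCODE v29 on GRCh38, in which 29248 symbols (99.36%) were found and 73 occurred more than once, and overlaps of at least 20% are given beside the named genes.

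Other settings, chosen in advance, were relative log expression and upper-quartile scaling, no filter, a filter of at least 1 CPM in all libraries of a group, DESeq2, limma voom with sample quality weights, robust empirical Bayes moderation, the replicate number as a block, leaving out each library, removing mitochondrially encoded genes, a 2-fold threshold, an adjusted p under 0.1, and the estimated correlation and fry for lists. Added after the data were seen were halving the counts of the 4 libraries of even counts or of all libraries, keeping those 4 libraries alone, leaving out both libraries numbered 2, removing genes at 0 in a whole group, and removing from each library a spline trend (5 degrees of freedom each) of GC content and transcript length.

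The gene test was tested on simulated data with 3 libraries against 3, in which 50 genes were changed at each fold among 13562 tested. It recovered 16% of genes changed 1.25-fold, 48% at 1.5-fold, 80% at 2-fold and 92% at 4-fold, with 4 false among 122 calls. A far larger share of genes was called in the data, so these rates need not hold there. A simulated list of 20 genes raised 1.5-fold was called by camera, and 0 of 30 random lists were, with the preset as with the estimated correlation. Genes were drawn independently of each other in this simulation. It therefore cannot show whether the preset correlation calls too many lists of correlated genes.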

Results

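Hemogenic endothelial cells, the endothelial cells from which blood cells arise, were grown from H1, an established human embryonic stem cell line, in co-culture with AGM-S3 stroma, with or without alpha lipoic acid at 100 µg/ml in the inducing medium. Alpha lipoic acid is an antioxidant and, bound to protein, a cofactor of mitochondrial dehydrogenase complexes. Cells with CD34, KDR and CD144 and without CD43 at their surface were sorted on day 8, and amplified polyA cDNA of aliquots of 1000 cells was sequenced in 3 untreated libraries and 3 lipoic acid libraries. The stated purpose was to learn how lipoic acid raises the output of blood progenitors from pluripotent stem cells, so the comparison asks which transcripts differ in the hemogenic endothelium before blood cells form. Total counts were 32034433, 30869907 and 30041494 in untreated replicates 1 to 3 and 40083619, 31404734 and 41351951 in lipoic acid replicates 1 to 3. Between 14668 and 15824 genes had a count in a library.

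The transcripts of the sort gate differed between the groups although every cell had passed the same gate. CD34 (chromosome 1, 207880972 to 207911402, GRCh38), a sialomucin of endothelium and blood progenitors, fell from 1451 ± 40.9 CPM in untreated libraries to 813 ± 10.3 CPM with lipoic acid (SD, n = 3 each). For CD34 the edgeR fit gave a 1.78-fold fall (adjusted p = 1.13e-06). CDH5, which encodes the adherens junction protein CD144, fell from 864 ± 127 to 556 ± 18.3 CPM (1.55-fold, adjusted p = 0.000344). KDR, a receptor for vascular endothelial growth factor, rose from 4115 ± 230 to 4813 ± 134 CPM, a 1.17-fold rise (adjusted p = 0.00409) that was not called once a trend with GC content and transcript length was removed (KDR log2 fold change 0.08 against 0.23, adjusted p = 0.328, and 0.000128 to 0.0259 under the other settings). SPN, which encodes CD43, had no count in any library, which allows up to 0.0393 CPM over the untreated and 0.053 CPM over the lipoic acid libraries. An exact two-sided permutation test of each of these levels cannot go below p = 0.1 with 3 libraries against 3, and CD34, CDH5 and KDR each reached that value.

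**Figure D1:**
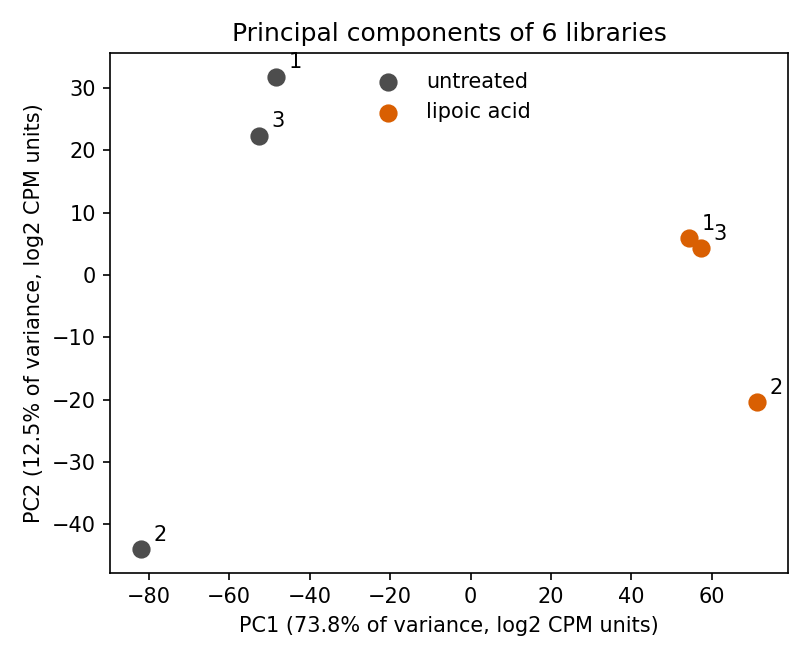
Scores of the 6 libraries on principal components 1 and 2 of log2 CPM, with untreated libraries in grey, lipoic acid libraries in orange and the replicate number beside each point. Component 1 held 73.8% of the variance and separated the groups, with untreated scores from -81.9 to -48.3 and lipoic acid scores from 54.3 to 71.2, and component 2 held 12.5% and set both libraries numbered 2 below the rest of their group.

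A large part of the measured transcriptome differed between the groups. Of 13780 tested genes, 3329 rose and 3205 fell, together 47.4%. By at least 2-fold, 1092 rose and 817 fell. The groups did not overlap in CPM for 8148 genes (59.1% of those tested), where chance gives 10%. With a GC content and transcript length trend removed from each library, 2468 genes rose and 3730 fell, so that 39.8% of calls were rises against 50.9% in the fit without that correction. In 4 of the libraries (all of the lipoic acid group and untreated replicate 1) over 99% of nonzero counts were even numbers, against 52.01% and 51.97% in untreated replicates 2 and 3. A fit without untreated replicate 1 thus sets untreated libraries without this excess against lipoic acid libraries that all have it. In such a fit the counting difference and treatment cannot be told apart. Within the 4 libraries of even counts alone, where untreated replicate 1 is the sole control and is assumed to vary like the others, 2880 genes rose and 2621 fell, and 4869 of the 6534 calls remained in the same direction. Of 36 gene lists with enough tested members, 12 were called by camera, 9 higher and 3 lower, and with an estimated correlation the calls of the stress response, endoplasmic reticulum, arterial and epithelial lists held.

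Genes of the integrated stress response rose together. Of the 26 members of the ATF4 and integrated stress response list, 21 rose, 0 fell and 5 did not pass, with a median log2 fold change of 0.89 (camera, adjusted p = 5.89e-39). SLC7A11 (chromosome 4, 138164097 to 138242349), the cystine importer that feeds glutathione synthesis, rose 8.83-fold from 41.7 ± 4.68 to 368 ± 3.21 CPM. ASNS, asparagine synthetase, rose 4.08-fold from 61.3 ± 1.33 to 250 ± 8.34 CPM, though 0.446 of its exonic length is shared with another annotated gene on the same strand. PSAT1, an enzyme of serine synthesis, rose 3.17-fold and WARS, the cytosolic tryptophanyl-tRNA synthetase, 2.51-fold. The highest adjusted p of these 4 genes was 2.08e-07. Adjusted over the list alone, the counts were again 21 and 0. The call held with an estimated correlation (adjusted p = 0.00986).

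Chaperone and unfolded protein response genes of the endoplasmic reticulum rose. All 19 members of that list rose, with a median log2 fold change of 0.91 (camera, adjusted p = 1.1e-36), and the same 19 did so adjusted over the list alone. HSPA5 (chromosome 9, 125234853 to 125241330), the main chaperone of the endoplasmic reticulum, rose 3.47-fold from 1169 ± 29.5 to 4050 ± 50.3 CPM (adjusted p = 1.6e-08). HSP90B1, its HSP90 chaperone, rose 2.40-fold from 2015 ± 90.4 to 4834 ± 101 CPM. HERPUD1, which acts in degradation of misfolded proteins, rose 2.73-fold and CRELD2, a stress-induced protein of the same compartment, 3.03-fold. The call held with an estimated correlation (adjusted p = 0.00986). Heat shock response genes did not follow: of 11 tested, 1 rose and 6 fell (7 adjusted over the list alone), among them HSPB1 (2.42-fold lower), DNAJA1 (1.40-fold), HSPA8 (1.26-fold) and HSPE1 (1.38-fold), and the list as a whole did not pass (median -0.24, adjusted p = 0.0501). The heat shock list was called lower in 8 of 20 other settings (0.0197 to 0.103 over all 20). Among them were the fit without lipoic acid replicate 2 (0.0294) and that without untreated replicate 1 (0.0197), where even counts and treatment coincide.

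Targets of NRF2, the transcription factor of the oxidant and electrophile response, also rose. Of 28 tested members 20 rose, 0 fell and 8 did not pass (median 0.63, camera adjusted p = 3.49e-16), and adjusted over the list alone 21 rose. The call was lost with adjusted p = 0.0615 with an estimated correlation. TXNRD1, cytosolic thioredoxin reductase, rose 3.42-fold from 200 ± 14.9 to 683 ± 24.3 CPM. NQO1, a quinone reductase, rose 2.60-fold from 169 ± 22.3 to 439 ± 13.2 CPM and GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis, 2.18-fold from 34.4 ± 2.42 to 75.1 ± 1.02 CPM. SLC7A11 belongs to this list as well as to the stress response list. Antioxidant enzymes as a class did not pass (32 tested, 4 rose, 14 fell, median -0.22, adjusted p = 0.508). Within that class TXNRD1 and SESN2 (1.61-fold) rose while MSRB2, a mitochondrial methionine sulfoxide reductase, fell 2.64-fold and GPX7 1.59-fold. Of 7 tested NADPH oxidase subunits 4 fell and 1 rose (adjusted p = 0.183 for the list), with NOX4 2.58-fold lower, RAC2 1.40-fold lower and RAC1 1.22-fold lower.

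**Figure D2:**
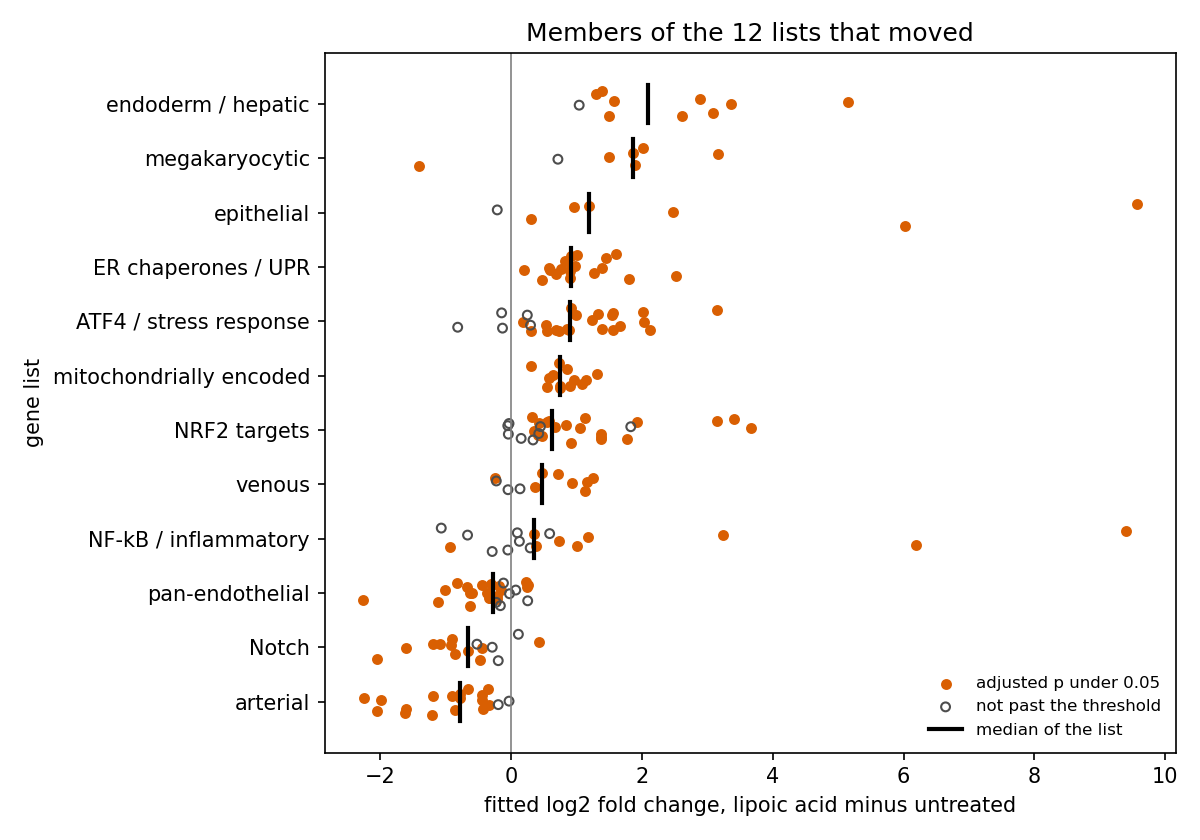
Fitted log2 fold change (lipoic acid minus untreated) of each tested member of the 12 called gene lists, sorted by the median of the list, with filled points for members with adjusted p under 0.05, open points for the others and a black bar at the median. All 19 endoplasmic reticulum genes lie above 0 and all filled arterial members, 17 of 19, lie below it.

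Arterial endothelial genes fell. Of 19 tested members 17 fell, 0 rose and 2 did not pass, also adjusted over the list alone (median -0.78, camera adjusted p = 7.2e-21; adjusted p = 0.00986 with an estimated correlation). GJA5 (chromosome 1, 147756199 to 147773362) and GJA4, the arterial gap junction connexins 40 and 37, fell 3.97-fold from 585 ± 5.92 to 147 ± 8.27 CPM and 3.04-fold from 831 ± 40.2 to 273 ± 29.6 CPM. An antisense gene covers 0.203 of the exonic length of GJA5, and strand use in counting was not given. CXCR4, the receptor for CXCL12, fell 3.09-fold from 1031 ± 59.5 to 333 ± 9.15 CPM, and HEY2, a Notch target repressor, 2.30-fold from 140 ± 9.95 to 61.0 ± 2.89 CPM. Of 15 tested Notch pathway genes 10 fell (11 adjusted over the list alone), 1 rose and 4 did not pass (median -0.66, camera adjusted p = 7.99e-05; adjusted p = 0.0623 with an estimated correlation). HEY2, HEY1 (1.58-fold), the ligand gene JAG2 (1.82-fold) and NOTCH3 (1.89-fold) were among those that fell, and HEY1, HEY2 and JAG2 are also on the arterial list.

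Venous and lymphatic endothelial genes moved the other way. Of 11 tested, 7 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone (median 0.48, camera adjusted p = 0.000599; adjusted p = 0.111 with an estimated correlation). NR2F2, the transcription factor of venous identity, rose 2.39-fold from 10.6 ± 0.983 to 25.2 ± 2.87 CPM. FLRT2 rose 2.20-fold, NT5E, which encodes CD73, 1.64-fold and NRP2, a co-receptor for lymphatic growth factors, 1.39-fold. Genes common to endothelium mostly fell: of 26, 17 fell (18 adjusted over the list alone), 3 rose and 6 did not pass (median -0.27, camera adjusted p = 3.46e-06; adjusted p = 0.111 with an estimated correlation). PLVAP fell 2.02-fold, ESAM 1.60-fold, SOX18 2.17-fold and CD34 as given. The libraries with lower arterial and endothelial genes were also those with higher epithelial, endoderm and mitochondrial transcripts.

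Transcription factors of blood emergence split. Of 24 tested, 5 rose, 9 fell and 10 did not pass, also adjusted over the list alone, and the list had no shared direction (camera adjusted p = 0.33, with a median of -0.10 but a mean of 0.10). RUNX1 (chromosome 21, 34787801 to 36004667), which is needed for the endothelial-to-hematopoietic transition, rose 5.46-fold from 2.63 ± 0.501 to 14.4 ± 0.531 CPM (adjusted p = 5.72e-06). MYB, a factor of definitive blood progenitors, fell 3.03-fold from 8.58 ± 1.22 to 2.83 ± 0.244 CPM. SOX17 and SOX18, endothelial factors, fell 2.32-fold and 2.17-fold. Of 13 tested HOXA and HOXB genes 4 rose, 1 fell and 8 did not pass (adjusted p = 0.102 for the list, called higher at 0.0333 with the GC content and length trend removed), with HOXA13 10.1-fold higher, HOXB6 1.55-fold higher and HOXB7 1.29-fold lower. HOXB6 overlaps other genes of its cluster by 0.166 of its exonic length on the same strand and by 0.163 on the other strand.

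**Figure D3:**
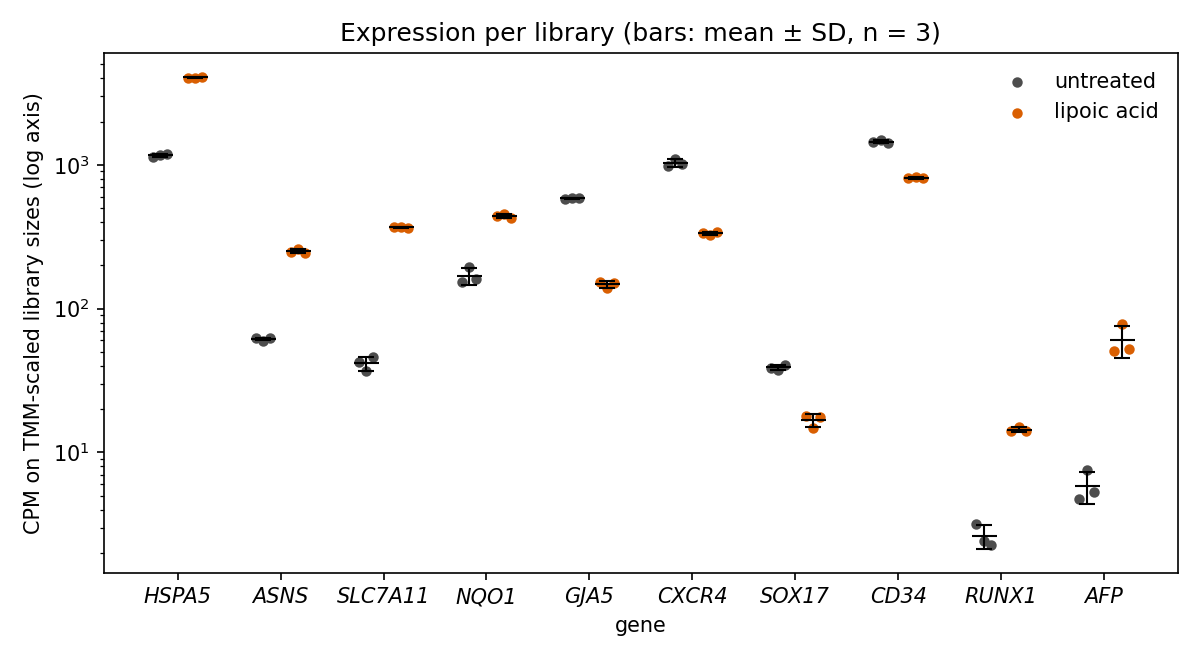
CPM on TMM-scaled library sizes (log axis) of 10 genes in each of the 3 untreated (grey) and 3 lipoic acid (orange) libraries, with mean and SD as bars. HSPA5, ASNS, SLC7A11, NQO1, RUNX1 and AFP lie higher and GJA5, CXCR4, SOX17 and CD34 lower in every lipoic acid library than in any untreated library.

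Markers of cell types that the gate was meant to exclude were measured in the same libraries. Of 10 tested endoderm and hepatic markers 9 rose and 0 fell (median 2.09, camera adjusted p = 3.01e-07; adjusted p = 0.231 with an estimated correlation). AFP, the fetal serum protein alpha-fetoprotein, rose 10.3-fold from 5.85 ± 1.47 to 60.1 ± 15.1 CPM, TTR, a thyroid hormone carrier, 6.10-fold to 50.5 CPM, APOB 7.42-fold and APOA2 2.82-fold. Of 7 tested epithelial markers 6 rose and 0 fell (median 1.19, camera adjusted p = 3.21e-07; adjusted p = 0.0457 with an estimated correlation), among them KRT8, 2.28-fold higher at 246 ± 23.6 CPM, and KRT19, 1.95-fold higher. EPCAM, an abundant epithelial adhesion gene, was not called (6.32 ± 1.59 and 5.45 ± 0.725 CPM, adjusted p = 0.444), and ALB, albumin, was too low to be tested, at 0.0205 CPM in untreated and 0.260 CPM in lipoic acid libraries. CDH1, which encodes E-cadherin, had 1 count over the untreated and, with even counts halved, 627 over the lipoic acid libraries. The ratio was 847 with a 95% counting interval of 151 to 33500, the 1 count being in untreated replicate 3. Of 7 tested megakaryocytic markers 5 rose and 1 fell (median 1.87, camera adjusted p = 0.00775; adjusted p = 0.153 with an estimated correlation), with SELP 4.05-fold, RAB27B 2.82-fold and PF4 8.99-fold higher (14.5-fold without untreated replicate 3, 15.0-fold in the 4 libraries of even counts). ITGB3, which shares 0.516 of its exonic length with another annotated gene, was 2.65-fold lower but lost its call without untreated replicate 2 (adjusted p = 0.0679) and without lipoic acid replicates 1 (0.086) or 3 (0.0932), and in the 4 libraries of even counts (0.143). SELP is also a gene of endothelial cells. Adjusted over the list alone, the counts of these lists were the same.

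Marker lists of the other excluded cell types were not called. Among mesenchymal markers 3 of 17 rose and 6 fell (adjusted p = 0.183), with MYL9 1.96-fold, THY1 1.51-fold and ACTA2 1.33-fold lower (an antisense gene covers 0.301 of the exons of ACTA2) and FBN1 1.28-fold higher (not called with the GC content and length trend removed, adjusted p = 0.0613). The mesenchymal list was called lower in 3 of 20 other settings, among them the 4 libraries of even counts (0.029) and the fit without both libraries numbered 2 (0.0403). Blood and myeloid markers had 10 tested members, 0 rises and 3 falls (adjusted p = 0.33), namely FCER1G (2.19-fold), RAC2 and LAPTM5 (1.19-fold), the last not called without lipoic acid replicate 3 (adjusted p = 0.0506). Pluripotency markers rose for 3 and fell for 2 of 7 (adjusted p = 0.634), with USP44 15.8-fold higher (40.0-fold without untreated replicate 1, 7.37-fold in the 4 libraries of even counts), LIN28A 1.68-fold and ZFP42 1.91-fold higher and GDF3 3.44-fold lower (not called in the 4 libraries of even counts, adjusted p = 0.104), and neural markers rose for 1 and fell for 2 of 5 (adjusted p = 0.596, median -0.03 and mean 0.14), with MAP2 2.91-fold higher and STMN2 1.55-fold and NES 1.40-fold lower. Cardiac markers rose for 2 and fell for 1 of 6 (2 fell adjusted over the list alone, adjusted p = 0.634 for the list), with TNNT2, cardiac troponin T, 7.46-fold lower (12.9-fold without lipoic acid replicate 1). The 2 cardiac rises were near the threshold: ACTN2 (adjusted p = 0.0437) was not called in 10 of 20 other settings, including each omission of 1 library (0.0523 to 0.105), and TTN (0.0473) in 5 of 20, among them without untreated replicate 3 (0.0765) and without lipoic acid replicates 1 (0.0924), 2 (0.104) or 3 (0.116). The filter left 3 of 17 erythroid markers, too few for a list test, and other settings that left 4 to 9 did not call the list (adjusted p 0.22 to 0.558). GYPB alone of the 3 passed, at 0 in every untreated library and at 0.521 ± 0.151 CPM with lipoic acid, at least 13.3-fold higher.

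Transcripts of the mitochondrial genome took a larger share of counts with lipoic acid, 4.79% ± 0.350 against 2.65% ± 0.184 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). All 13 protein-coding mitochondrial genes rose, also adjusted over the list alone (median 0.74, camera adjusted p = 8.9e-14; adjusted p = 0.231 with an estimated correlation), with MT-ND4L 2.48-fold, MT-CO3 2.12-fold, MT-CO1 1.95-fold and MT-ND4 1.86-fold higher. Nuclear-encoded respiratory chain genes did not: 4 of 58 rose and 17 fell (16 adjusted over the list alone), with CYC1 1.65-fold and UQCRFS1 1.63-fold lower, NDUFS1 1.24-fold higher (not called with the GC content and length trend removed, adjusted p = 0.417) and no list call (median -0.18, adjusted p = 0.0679), except without untreated replicate 1 (0.0314) or 3 (0.0168), where the respiratory chain list was called lower. Without untreated replicate 1, even counts and treatment coincide. Lipoate synthesis genes and the lipoylated complexes had 6 rises and 4 falls among 20 (adjusted p = 0.725, median 0.08 and mean -0.08), with DLAT 1.31-fold, PDK1 1.37-fold (not called with that trend removed, adjusted p = 0.0596) and PDP2 1.70-fold higher and PDK3 1.56-fold lower. Glycolytic genes had 4 rises and 7 falls (8 adjusted over the list alone) among 21 (adjusted p = 0.268), and SLC2A1, the glucose transporter GLUT1, fell 1.62-fold from 2306 ± 39.6 to 1427 ± 43.9 CPM, SLC16A1, a lactate transporter, 1.51-fold and PKM, pyruvate kinase, 1.28-fold.

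Inflammatory genes downstream of NF-kB rose for 8 and fell for 1 of 17 tested members, also adjusted over the list alone (median 0.35, also with the member at 0 in the untreated group set at its bound, camera adjusted p = 0.0358; adjusted p = 0.193 with an estimated correlation). The NF-kB list was not called without untreated replicate 3 (adjusted p = 0.0693) or with robust empirical Bayes moderation (0.056), and the other settings with the preset correlation gave 9.23e-05 to 0.0485. CXCL8, a neutrophil chemokine, rose from 0.569 ± 0.554 to 42.6 ± 8.96 CPM, a 73.0-fold rise that became 142-fold without untreated replicate 1 and 38.5-fold in the 4 libraries of even counts. IL1B had no count in the untreated group and was at least 62.7-fold higher at 2.46 ± 0.992 CPM, CXCL1 rose 9.44-fold, and TNFAIP3, an inhibitor of the pathway, rose 1.66-fold from 115 ± 2.81 to 192 ± 3.98 CPM. Interferon-stimulated genes rose for 5 and fell for 5 of 23 (adjusted p = 0.634, median -0.07 and mean 0.42), with BST2 1.68-fold and IFIT2 2.01-fold higher and ISG15 1.56-fold lower. GBP1, with no untreated count, was another of the rises. Its fitted log2 fold change of 11.0 entered the interferon mean without a bound. Immediate early genes rose for 7 and fell for 4 of 20 (6 fell adjusted over the list alone, adjusted p = 0.213 for the list), with ATF3 4.05-fold, MYC 3.22-fold and JUN 1.54-fold higher and JUNB 1.94-fold lower.

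Hypoxia-inducible genes rose for 12 and fell for 4 of 24 and did not pass as a list (median 0.16, adjusted p = 0.0501), but the hypoxia list was called higher in 14 of 20 other settings (adjusted p 0.00773 to 0.199), among them each omission of 1 library except untreated replicate 3. Members included STC2 1.88-fold and DDIT4 2.35-fold higher and SLC2A1 and EGLN3 (1.65-fold) lower. STC2 and DDIT4 belong to the stress response list as well, SLC2A1 and EGLN3 do not. An antisense gene covers 0.412 of the exonic length of DDIT4. Cholesterol synthesis genes rose for 8 and fell for 1 of 19 (median 0.19, adjusted p = 0.082, called higher in 2 of 20 other settings, at 0.0352 with limma voom), with STARD4 1.80-fold and HMGCS1 1.59-fold higher. Among TGF-beta and BMP genes 8 of 24 rose and 11 fell (13 adjusted over the list alone, adjusted p = 0.183 for the list), with ID1 1.75-fold, SKIL 1.92-fold and ENG 1.52-fold lower and BMP6 1.50-fold higher. Wnt targets rose for 3 and fell for 3 of 9 (4 fell adjusted over the list alone, adjusted p = 0.634 for the list, median 0.13 and mean -0.42), with LEF1 1.62-fold and ZNRF3 1.80-fold higher, SFRP1 1.38-fold lower and NKD1 17.8-fold lower (31.8-fold without lipoic acid replicate 3). Metal-handling genes rose for 5 and fell for 2 of 10 (adjusted p = 0.634), with TFRC, the transferrin receptor, 1.74-fold higher and SLC40A1, the iron exporter ferroportin, 1.57-fold lower. The counts adjusted over the list alone were the same for the hypoxia, cholesterol, metal, interferon, lipoate, antioxidant, NADPH oxidase, HOX, mesenchymal, blood, pluripotency, neural and erythroid lists.

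Cell cycle genes did not pass as lists. S-phase genes rose for 10 and fell for 8 of 42 (7 fell adjusted over the list alone, adjusted p = 0.426, median 0.05 and mean -0.05) and G2/M genes rose for 15 (14 adjusted over the list alone) and fell for 4 of 52 (adjusted p = 0.333; called higher without untreated replicate 2, 0.0348, and in the 4 libraries of even counts, 0.0124). CDC6, a licensing factor of replication, rose 3.66-fold from 8.02 ± 1.44 to 29.3 ± 2.73 CPM, ATAD2 2.64-fold and CENPE 4.88-fold, while CDC25C fell 3.20-fold. E2F8 had no count with lipoic acid and was at least 27.1-fold lower than its 1.44 ± 0.357 CPM in untreated libraries. Its fitted log2 fold change of -8.63 entered the S-phase mean without a bound. Targets of p53 rose for 6 (7 adjusted over the list alone) and fell for 5 of 22 (adjusted p = 0.697), with SESN2 1.61-fold and TNFRSF10B 1.24-fold higher (TNFRSF10B not called with the GC content and length trend removed, adjusted p = 0.0579) and SPATA18 1.69-fold lower. Ribosomal protein genes rose for 3 and fell for 16 of 79 (10 fell adjusted over the list alone, camera adjusted p = 0.191), RPL13 by 1.41-fold and RPL38 by 1.37-fold. The ribosomal list was called lower without untreated replicate 1 (camera adjusted p = 0.016), where even counts and treatment coincide. The share of counts in ribosomal protein genes was 3.63% ± 0.261 in untreated and 3.55% ± 0.0800 in lipoic acid libraries (exact permutation p = 0.8).

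Among called genes with at least 5 CPM in the higher group and no overlap between groups, those with the largest rises were nearly silent in untreated cells. GBP1, an interferon-inducible GTPase, TOX3, CALB1, ST8SIA5 and STK32A had no count in any untreated library and were at least 196-fold, 146-fold, 142-fold, 131-fold and 129-fold higher with lipoic acid, at 7.71 ± 2.10, 5.73 ± 1.60, 5.59 ± 0.927, 5.15 ± 0.808 and 5.05 ± 1.66 CPM. The floor of 3 independent counts, even counts halved, was taken over the untreated group. ESRP1, an epithelial splicing regulator, reached 12.9 ± 3.51 CPM from 0.195 ± 0.200 (64.9-fold, 130-fold without untreated replicate 3). SLC7A3, a cationic amino acid transporter, reached 7.55 ± 1.50 CPM from 0.0854 ± 0.0741 (84.0-fold). FGA, the fibrinogen alpha chain, reached 11.3 ± 3.53 CPM from 0.125 ± 0.162 (85.5-fold, 309-fold without untreated replicate 1, 36.4-fold in the 4 libraries of even counts) and ALDH1A1, a retinaldehyde dehydrogenase, 7.17 ± 1.87 CPM from 0.0665 ± 0.0665 (104-fold, 202-fold without untreated replicate 3; untreated replicate 1 had no count). GABRP reached 5.33 ± 4.29 CPM from 0.0665 ± 0.115, with all untreated counts in replicate 3, and was not called by limma voom with quality weights (adjusted p = 0.121, and 5.16e-06 to 0.0303 under the other settings).

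Among the largest falls under the same limits of level and overlap, DHRS2, a short-chain dehydrogenase, fell from 21.7 ± 8.27 to 0.366 ± 0.318 CPM (56.0-fold, 97.9-fold without lipoic acid replicate 1). DIO3, which inactivates thyroid hormone, fell 18.9-fold from 18.2 ± 1.22 to 0.949 ± 0.354 CPM and SLN, which encodes the calcium pump regulator sarcolipin, 13.4-fold from 34.5 ± 2.76 to 2.57 ± 0.775 CPM. NCAM2 fell 29.2-fold (19.2-fold without lipoic acid replicate 1 and 102-fold without replicate 3), CLIC5 11.7-fold (21.7-fold without lipoic acid replicate 1), MFAP4 8.59-fold, SIRPB2 7.15-fold and OASL 7.14-fold. The remaining 4 of the 12 are uncertain. IL3RA, in the pseudoautosomal region, fell 42.8-fold, but 7.86-fold without untreated replicate 2 and 6.98-fold in the 4 libraries of even counts, and its untreated level was 14.6 ± 20.7 CPM. HRAS fell 20.7-fold, but 6.73-fold without untreated replicate 2 and 10.9-fold in the 4 libraries of even counts, and neither gene was called with robust empirical Bayes moderation (adjusted p = 0.0592 and 0.0535). HLA-E and FLOT1, of the major histocompatibility complex region, fell 8.37-fold and 7.17-fold, but only 3.24-fold and 1.59-fold within the 4 libraries of even counts, where FLOT1 was not called (adjusted p = 0.416, and 5.77e-07 to 0.019 under the other settings). FLOT1 stood at 1.17, 6.15 and 8.51 CPM in untreated replicates 1 to 3 and HLA-E at 5.75, 18.9 and 19.98 CPM. Whether reads with several alignments were counted alike in all libraries was not given, which leaves the folds of HLA-E and FLOT1 uncertain.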

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

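Halved counts, the 4 libraries of even counts alone, leaving out both libraries numbered 2, the GC content and length trend and removal of genes at 0 in a group were chosen after the results were seen, and the other alternatives were planned. No called list or named gene reversed. At a 2-fold threshold 1092 genes were higher and 817 lower, fewer by construction. With an estimated correlation 4 lists were called and with fry, which does not compare a list with other genes, 25. Leaving out 1 library gave 2669 (without lipoic acid replicate 3) to 3569 (without untreated replicate 2) genes higher, 2386 to 3448 lower (the same libraries), and 12 to 16 lists. Of the comparisons of the 12 called lists with an alternative, 253 kept direction and call and 10 lost the call; of those for 157 named genes, 3093 kept both and 32 lost the call.

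Outside the 2-fold threshold, the 3 counts (genes higher, genes lower and, apart from the list test itself, lists called) stayed within 1.5 times their first value. DESeq2 gave 3575 higher and 3339 lower, limma voom 3772 and 3713, and the GC content and length trend 2468 and 3730, for which the cause of the shift was not tested. In the libraries of even counts 18 calls changed sign and none was called in the opposite direction, and with the trend removed 42 did so with none called in the opposite direction. At the simulated depth and number of libraries, 48% of 1.5-fold changes were recovered against 92% at 4-fold. The simulation changed 50 genes at each fold among 13562, with 122 calls, whereas 47.4% of tested genes were called in the data. The adjusted p cutoff therefore differs, and these rates do not give the sensitivity of the real comparison. The simulation used a single depth. In the data, halving the counts of the libraries of even counts gave 3244 higher and 3183 lower, and halving all counts 3280 and 3097.

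With the replicate number as a replicate block, 3354 genes were higher and 3203 lower, 6190 of the 6534 calls were kept, and 16 lists were called, adding hypoxia, heat shock, cholesterol and mesenchymal genes. Libraries with the same number deviated together only weakly (r across genes 0.0598 to 0.0783), although 6 of 6 correlated best with their own number, which is a hint from the data and not from the design.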

Other observations

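Tests of other splits, of shared preparation (all libraries, or libraries 1 and 3), of the mitochondrial share, of a lower endothelial share and of the synthetase genes without shared members were chosen only after the result was seen, as were the 5 added gene lists, whose predictions were written before their values.

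The number of genes called, 6534, was compared with the 9 other splits of the 6 libraries into 3 and 3. The real split was the only 1 of 10 with as many, the highest other calling 0 (edgeR, adjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split mixes both groups on each side, so the difference between groups widens its spread and few calls could follow. The comparison therefore decides nothing about the cause of the calls.

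Counts were 0 in every library of one group and 10 or more in every library of the other for 221 genes, 147 silent in untreated and 74 silent in lipoic acid libraries, of which 177 were protein coding. The smallest number of independent counts expected in the silent group was 19.5, but the minimum of 10 counts fixes this value above the floor of 3, so it decides nothing about counting error. Libraries of a group may share one preparation of cDNA or one sort: of genes at 1 to 2 CPM in a library, at most 0.201% were at 0 between libraries 1 and 3 of a group, against at least 2.38% across groups. Genes at 1 to 2 CPM in a library numbered 2 were at 0 in its fellows as rarely (at most 0.221%). In the other direction, into the libraries numbered 2, the highest share within groups was 3.56% in untreated replicate 2 and 0.954% in lipoic acid replicate 2. Across groups 13.3% to 15.8% were at 0 in untreated replicate 2, and the lowest share across groups was 2.38%. The shares of 3.56% and 2.38% are picked extremes over the same 926 genes, which a Fisher test (p = 0.171) treats as separate sets. That test cannot decide, so sharing by all 3 libraries of a group stays undecided. A response to lipoic acid stays open beside it, untested, since preparation and treatment would fall on the same groups.

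The rise of the ATF4, endoplasmic reticulum chaperone and NRF2 lists and the fall of the arterial list were set against 3 technical explanations. The smallest ratio of a list's median to its first value was 0.873 with a GC content and length trend removed and 0.996 in the 4 libraries of even counts, where a whole cause would bring it to 0.5 or less. The larger mitochondrial share can shift all other genes by at most 0.0384 (log2) between any 2 libraries, against list medians of 0.63 or more in size. These values argue against each as the whole cause. A shared preparation within groups, as above, stays open for these lists too, so a stress response to lipoic acid remains a hypothesis.

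Higher epithelial and endoderm or hepatic markers with lipoic acid may come from admixed epithelial or hepatic cells. Of 8 abundant transcripts (AFP, TTR, APOA1, APOA2, EPCAM, KRT8, KRT18 and KRT19), 0 were called lower or at 3 counts or fewer, but these genes belong to the lists that prompted the test, so this value could hardly differ and decides nothing about admixed cells. EPCAM did not rise (log2 fold change -0.21, edgeR adjusted p = 0.444) and SERPINA1 had no count with lipoic acid. ALB stood at 0.0205 CPM in untreated and 0.260 CPM in lipoic acid libraries, too low to be tested. Of tested markers, 9 of 10 endoderm and hepatic and 6 of 7 epithelial ones rose, and CDH1 went from 1 count to 627, even counts halved. The gate on CD34, KDR and CD144 was meant to exclude such cells, but how well it did so was not tested. Admixed cells therefore stay open. A lower share of endothelial cells with every other cell type higher alike was set against 17 mesenchymal markers, of which 6 fell and 3 rose. That list was not called (camera adjusted p = 0.183, called lower in 3 of 20 settings at 0.0285 to 0.0403). The bound on falls was set after these values were seen. Of all 13780 tested genes 3205 fell, so some falls would be found in most lists. Mesenchymal markers thus did not rise as a set, but the number of falls does not decide about a lower endothelial share. Expression of these genes by the sorted cells was not tested.

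Of 20 cytosolic aminoacyl-tRNA synthetase genes 11 rose and 2 fell (camera adjusted p = 1.4e-07; 0.0325 with an estimated correlation), WARS by 2.51-fold, AARS 2.36-fold and IARS 2.26-fold. Without WARS, SARS and GARS, which are also on the ATF4 list, 8 of 17 rose and 2 fell (adjusted p = 0.000951; 0.0793 with an estimated correlation). Of 16 mitochondrial synthetase genes 6 rose and 2 fell (adjusted p = 0.435). The medians of the full lists differed by 0.257 (log2, interval over resampled members -0.270 to 0.904), so an ATF4 program limited to cytosolic synthetases is not decided. Of 31 proteasome genes 4 rose and 9 fell (camera adjusted p = 0.269). Their median was -0.144 (interval over resampled members -0.203 to -0.0776), so the predicted rise of the set was not seen. That interval covers the spread between members and not between libraries. Whether an NRF1 or NRF2 program reached some of them is therefore not decided. Of 34 lysosome and autophagy genes 11 rose and 11 fell (median -0.0172, adjusted p = 0.891), which decides nothing. Of 17 basement membrane genes 9 fell and 1 rose (median -0.333, adjusted p = 0.00544; 0.769 with an estimated correlation), consistent with matrix genes falling with the arterial genes only under the preset correlation.

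A library lay at least 2-fold from both fellows (maximum of at least 5 CPM) for 46, 77 and 16 genes in untreated replicates 1 to 3 and for 11, 25 and 11 genes in lipoic acid replicates 1 to 3. Of these, 24, 28 and 6 and then 0, 7 and 0 were among the called genes (edgeR). HMGN2 stood at 19.1, 121 and 104 CPM in untreated replicates 1 to 3 and at 20.4, 21.7 and 21.4 CPM with lipoic acid. TUBB stood at 10.6, 38.8 and 40.5 CPM and at 7.47, 6.62 and 7.37 CPM. Both genes were called lower (edgeR adjusted p = 0.00905 for HMGN2 and 0.002025 for TUBB). Untreated replicate 1, of even counts like the lipoic acid libraries, lay far nearer to those libraries than to its fellows. Whether the counting difference gave these calls was not tested.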
